A study of Rattus norvegicus with 48 samples.

How the data were processed

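Total RNA of left ventricle and kidney from 24 male Dahl salt-sensitive rats had been hybridized to Illumina rat bead arrays with 22523 probes, 48 arrays in all, 6 for each of 4 groups in 2 tissues. The array titles name the heart samples lateral ventricle and the series design names them left ventricular; they are called left ventricle here. Per the labels the diets began at 6 weeks of age and lasted 8 weeks, the antibody was given at week 7 and 15 weeks of age, and the age was 16 weeks; these ages do not add up with the weeks on the diet. The authors deposited the signal intensity of each probe and array, exported with GenomeStudio 2011.1 per their processing notes, without a visible background subtraction. Per the file headers the same table held a detection p-value for each probe and array. The authors also deposited a normalized table, whose values are a z score per array: the log of the signal minus its mean over the probes of the array, divided by its SD, which matched to within 0.00649. The series matrix held the same scores, with a largest difference of 0, and was not analysed separately.

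Intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc estimated the background of each array from the detection p-values, added an offset of 16, took log2 and normalized quantiles over the 24 arrays of a tissue, or over all 48 arrays for comparisons between tissues. A probe was tested in a tissue if its detection p was under 0.01 on at least 6 arrays. Of several such probes with the same gene symbol, the probe with the highest mean stood for the gene. The platform table named 13793 probes, of which 13752 had a gene ID in the GRCr8 gene table, and 0 symbols needed updating; 8730 unnamed probes were kept under their own identifiers and counted as genes. This left 6517 genes in ventricle, 9800 in kidney and 6200 in both.

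The means of the 4 groups of a tissue were fitted with lmFit, with the spread pooled over the groups, and compared with eBayes with a trend in the prior. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05 within each comparison. High salt was compared with low salt under control IgG, the antibody with control IgG on each diet, and the antibody effects of the diets with each other. Between tissues, 8 group means were fitted and the differences of the salt effects and of the antibody effects on high salt were tested. The same number within a group names the same animal in both tissues: over 24 pairs, values centred on their group had a median r of 0.0395 between the tissues of the same animal and -0.00755 between animals, so the fit with the animal as a block is given beside the unblocked counts. The number of arrays limits the precision of all values, and signal over background differed between groups as given with the results. The files name no array chip or day, so a batch could not be looked for.

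A total of 39 gene lists of pathways, cell types and reference genes were fixed before the data were examined, each tested with camera at a preset correlation of 0.01 when at least 5 members were tested, with adjustment over the lists of a comparison. This made 31 lists in ventricle and 38 in kidney. Camera was repeated with an estimated correlation for every list, and no list passed with it. Each list was also counted with adjustment over the list alone. Genes named here were chosen by a rule fixed at the same time: the 10 higher and 10 lower named genes with the largest change in each comparison (the 5 smallest p-values where none passed), the 4 members with the smallest p of each list that passed, and 16 fixed genes of fibrosis, heart and kidney where measured. The text gives a part of these. A fold against a group with no detected array is a lower bound, computed against the detection limit.

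The correlation of salt and antibody effects across genes was compared with 100 simulations without effects that share the high salt control arrays, and with those arrays split in every way into 3 and 3. For each count, 100 splits of the arrays were drawn with seed 1. The procedure was tested on simulated data in which 200 genes were changed. With equal spread in all groups, 76% or more of the genes changed 2-fold were called in each ventricle or kidney comparison of the diets or of the antibody on high salt, and at most 8.99% of the calls were false. For the antibody on low salt 75% were called in ventricle and 92% in kidney, for the difference between diets 40.5% and 69%, and between tissues 40.5% for high salt and 47% for the antibody, so a gene that did not pass in the last 2 kinds of comparison is weak evidence of no difference. A limit on false calls set for the test was not met when each group kept its own spread, and that limit was then applied to equal spread alone. With the groups' own spread the share of false calls was 9.13% to 10.6% for high salt in ventricle, 38.8% to 41.9% for the antibody on high salt in ventricle, 21.8% to 24.9% for high salt in kidney, 10.8% to 12.5% for the antibody on high salt in kidney and 40.3% to 49.7% for the antibody between tissues. It was 13.6% to 19.2% for high salt between tissues. For the antibody on low salt it was 1.49% to 1.80% in ventricle and 18.5% to 21.1% in kidney. For the difference between diets it was 7.79% to 11.3% in ventricle and 8.07% to 8.76% in kidney. Of 32 simulated lists with changed genes 32 passed camera, and of 32 random lists 0 passed. The simulated genes varied independently of each other, so this does not test the preset correlation on lists whose genes vary together.

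Alternatives were no background correction, median scaling in place of quantiles, the authors' normalized values, no filter, detection on all arrays, each probe on its own, array weights, a fit of only the groups compared, another set of arrays normalized together, and replicate numbers as a block. Further alternatives were chosen after seeing the data: the number of detected probes as a covariate, only high salt ventricle arrays of overlapping brightness, 2 kidney control arrays left out together or singly for their low correlation with their groups (median r 0.947 and 0.931, all others 0.976 or more), and the mean of the adipocyte list as a covariate. All 48 arrays were used. Figures were drawn with matplotlib 3.10.9.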

Results

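Gene expression was measured on 48 Illumina rat arrays from 24 male Dahl salt-sensitive rats, an inbred strain whose blood pressure rises on a high salt diet. Each animal gave a left ventricle sample and a kidney sample. The diets held 0.1% or 8% NaCl and were given for 8 weeks. Each animal received an injection of 50 µg/kg of either a control IgG or a monoclonal antibody to marinobufagenin at week 7. Marinobufagenin is an endogenous steroid that inhibits the Na/K-ATPase. The 4 groups of each tissue held 6 animals each. The comparisons ask, in each tissue, which genes differed with high salt under control IgG, which differed with the antibody on each diet, and whether the antibody effect differed between diets. TGF-beta and fibrosis genes were among those fixed for naming, since the series is about profibrotic signaling. All changes below are on the log2 scale with their standard error, from 6 arrays per group, except that changes in the authors' normalized values are differences of z scores. The standard error uses a spread pooled over all groups of the fit. It is too small where the groups compared spread more than the others. Fhl1 in ventricle, for example, had SDs of 1.56 (antibody) and 0.67 (control) on high salt, and of 0.27 and 0.29 on low salt.

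The ventricle arrays differed in brightness by diet. High salt ventricle arrays detected 4026 ± 837 probes with control IgG and 3010 ± 646 with the antibody (SD, n = 6), out of 22523 on the array. Low salt ventricle arrays detected 6608 ± 364 and 6258 ± 164 (SD, n = 6). Each high salt ventricle array, with at most 5576 detected probes, lay below each low salt ventricle array, with at least 6091. Diet and array brightness therefore cannot be told apart in the ventricle. Kidney arrays detected 8388 to 9854 probes, and the diets overlapped. The number of arrays limits the precision of every value.

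**Figure D1:**
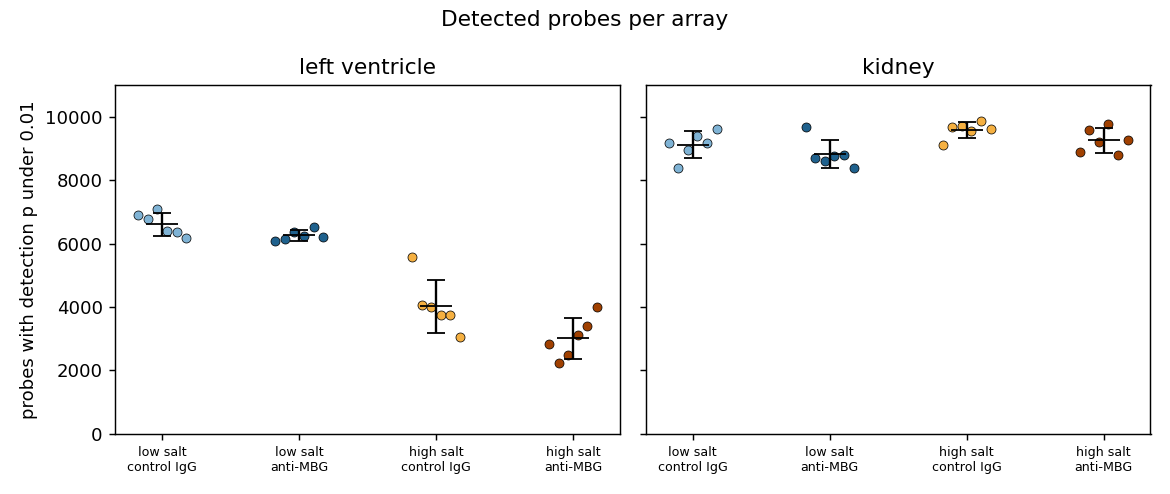
Number of probes with a detection p under 0.01 on each array, by tissue and group; points are arrays, horizontal lines are means and bars are SDs (n = 6). The high salt ventricle arrays span 2220 to 5576 detected probes and the low salt ventricle arrays 6091 to 7088, while kidney arrays span 8388 to 9854.

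In the left ventricle, the natriuretic peptide genes, which cardiomyocytes express under load, had higher normalized values on high salt. As all high salt arrays were dimmer, the changes in this paragraph may come from the diet or from brightness. Nppa (gene ID 24602; chromosome 5, 163712184 to 163713493 in GRCr8) rose by 2.12 ± 0.30 (adjusted p = 6.40e-07) and Nppb by 1.43 ± 0.19 (adjusted p = 2.76e-07). Tgfb1, the gene of the profibrotic cytokine TGF-beta 1, rose by 1.80 ± 0.25 (adjusted p = 3.50e-07). Tgfb1 was above background on 5 of 6 control IgG arrays of each diet, with means of 7.88 on high salt and 6.08 on low salt. On high salt with the antibody its mean was 6.99 with only 1 of 6 arrays above background. Values of Tgfb1 near background thus lay higher on the dimmer high salt arrays, and a part of its rise may be this shift. Spp1, the matrix protein osteopontin, rose by 1.64 ± 0.39, and Fli1, an ETS transcription factor that represses collagen genes, rose by 1.21 ± 0.20. Bgn, a small matrix proteoglycan, rose by 2.75 ± 0.30. For Nppa, Nppb, Tgfb1, Fli1 and Bgn, each of the 6 high salt arrays lay above each of the 6 low salt arrays. The diets were separated in the same way by array brightness, so this separation does not tell an effect of the diet from brightness. Ccn2 (0.49 ± 0.25), Timp1 (0.58 ± 0.34), Fn1 (0.39 ± 0.37), Col3a1 (0.25 ± 0.24) and Myh7 (0.18 ± 0.14) did not pass the test.

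Genes of the contractile apparatus and of mitochondrial respiration had lower normalized values in the ventricle on high salt. Of 18 measured genes of adult cardiomyocyte contraction and ion handling, 13 fell, 2 rose and 3 did not pass, with the same counts of 13 and 2 adjusted over the list alone. Myl3, a myosin light chain, fell by 2.60 ± 0.22, Mybpc3 fell by 1.71 ± 0.15 and Tnnt2, cardiac troponin T, fell by 1.54 ± 0.11. The list had a camera adjusted p = 0.00915 and an adjusted p = 0.898 with an estimated correlation. Of 26 oxidative phosphorylation genes, 19 fell, 2 rose and 5 did not pass (19 and 3 adjusted over the list alone), among them Cox8a, which fell by 1.76 ± 0.14, and Ndufs3, which fell by 1.65 ± 0.15. This list had a camera adjusted p = 0.00270 and an adjusted p = 0.898 with an estimated correlation. The mean of the cardiomyocyte list was -0.78 and that of the oxidative phosphorylation list was -0.70. With the authors' normalized values, however, both tests turned to the other direction, at mean z score differences of -0.25 and 0.16.

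In all, 4156 of 6517 genes tested in the ventricle changed with high salt, 1597 higher and 2559 lower (limma, adjusted p under 0.05). With the number of detected probes as a covariate, 97 genes passed, and Nppa (2.06), Nppb (0.54), Tgfb1 (1.59), Spp1 (0.98), Fli1 (0.62), Bgn (0.55), Myl3 (-1.05), Mybpc3 (-0.83) and Ndufs3 (-0.72) no longer did. Among genes detected on all 24 arrays 1373 passed, 882 higher and 491 lower, so that the balance turned to higher genes, and median scaling moved the median of all genes from -0.23 to 0.27 and the share of higher genes from 38.4% to 64.7%.

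With the antibody on high salt, the ventricle had less Fhl1, a LIM-domain gene of hypertrophied myocardium, and less Col8a1, a short-chain collagen. Fhl1 (gene ID 25177; chromosome X, 139592794 to 139652290) fell by 2.90 ± 0.42 (adjusted p = 4.37e-05) and Col8a1 fell by 2.59 ± 0.35 (adjusted p = 1.72e-05). In both genes the 6 antibody arrays lay below the 6 control arrays, and both passed under every alternative that tested them. All 6 control arrays were above background for both genes, but only 3 antibody arrays for Fhl1 and 1 for Col8a1, so the sizes of these fitted changes rest on values at background. In the fit Tgfb1 fell by 0.89 ± 0.25 (adjusted p = 0.0122), Spp1 fell by 1.35 ± 0.39 (adjusted p = 0.0153) and Ccn2, a matricellular gene induced by TGF-beta, fell by 0.69 ± 0.25 (adjusted p = 0.0484). Tgfb1 was above background on 1 of 6 antibody and 5 of 6 control arrays, Spp1 on 2 and 6, and Ccn2 on all 6 of both groups. Fn1, fibronectin, was above background on 3 of 6 control arrays and 0 of 6 antibody arrays, so no fold is given. Nppa (-0.67 ± 0.30), Nppb (0.40 ± 0.19), Col3a1 (-0.23 ± 0.24), Timp1 (-0.58 ± 0.34) and Fli1 (-0.28 ± 0.20) did not pass.

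**Figure D2:**
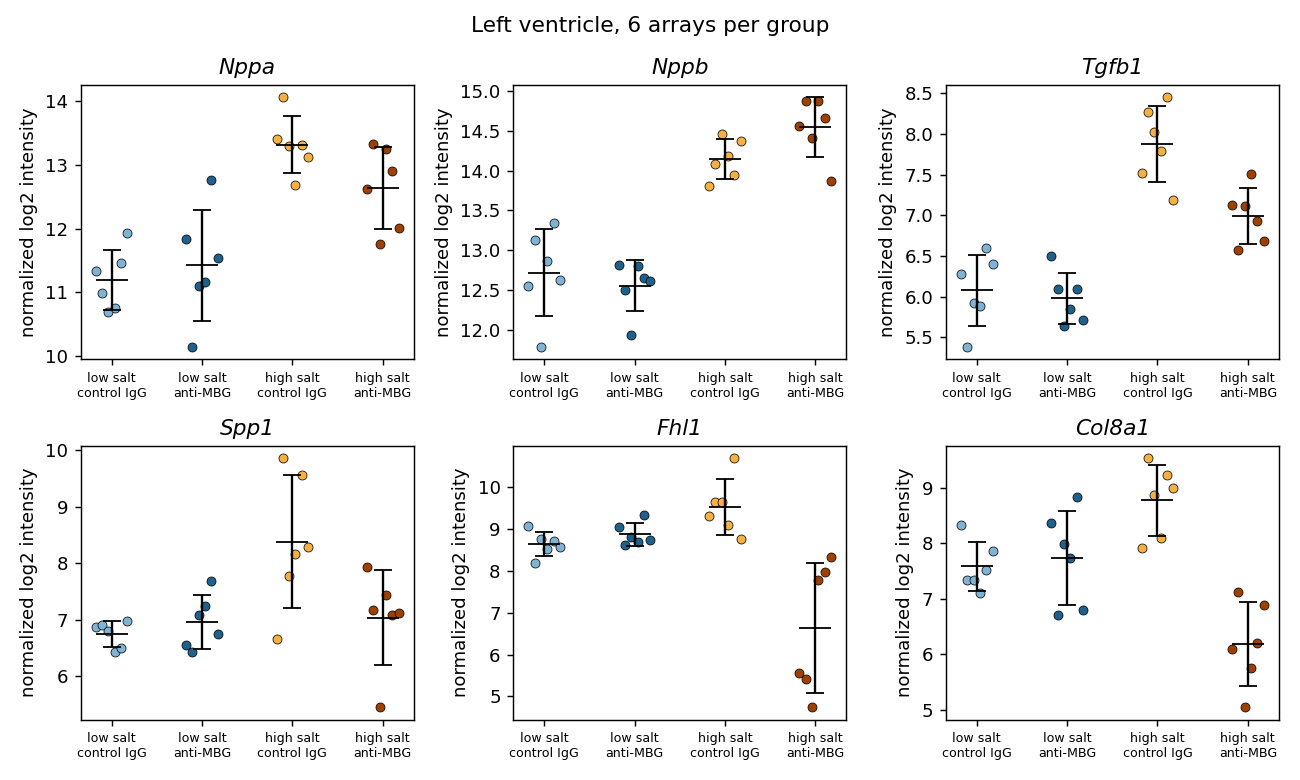
Normalized log2 intensity of 6 genes on each left ventricle array, by diet and antibody; points are arrays, horizontal lines are means and bars are SDs (n = 6). Nppa, Nppb and Tgfb1 were higher on high salt under control IgG, and Fhl1 and Col8a1 were lower in each high salt antibody array than in each high salt control array.

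Some macrophage, collagen and TGF-beta induced genes had lower fitted values in the ventricle with the antibody on high salt, several of them near background. Of 15 macrophage and myeloid genes 8 fell, 0 rose and 7 did not pass (10 lower adjusted over the list alone), among them the mannose receptor Mrc1, which fell by 2.05 ± 0.40 and was above background on 2 of 6 antibody and 6 of 6 control arrays. Among other genes called in these lists, C1qc was above background on 1 antibody and 4 control arrays and Lox on 0 and 5, while Plod2 was above background on all 6 arrays of both groups. Cd14 and Loxl2 were called although no array of either group was above background, since they were tested through their detection on low salt arrays. The list mean was -0.77, with a camera adjusted p = 0.0110 and an adjusted p = 0.522 with an estimated correlation. TGF-beta induced genes had 7 of 16 lower (8 adjusted over the list alone; mean -0.59), collagen genes 6 of 17 lower (7 adjusted over the list alone; mean -0.60) and cardiac stress genes 5 of 12 lower (9 adjusted over the list alone; mean -0.73), with 0 higher in each. These 3 lists had a camera adjusted p = 0.0266 each and an adjusted p = 0.522 with an estimated correlation. The endoplasmic reticulum stress list was higher, with 2 of 11 members higher (1 adjusted over the list alone), a mean of 0.15, a camera adjusted p = 0.0491 and an adjusted p = 0.522 with an estimated correlation; Xbp1 rose by 0.43 ± 0.14 and Ddit3 rose by 0.43 ± 0.16. With median scaling the means of the macrophage, TGF-beta and collagen lists were 0.04, 0.13 and 0.04, below the median of all genes of 0.46. With the authors' values, in z scores, the stress list had a mean of -0.03 and the TGF-beta list (-0.28) no longer passed.

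In all, 1376 of 6517 ventricle genes changed with the antibody on high salt, 391 higher and 985 lower. Of the 391 higher genes, 280 were also raised by high salt and 36 were lowered by it. Of the 985 lower genes, 143 were raised by high salt and 339 were lowered by it. Genes that changed in both comparisons thus moved more often in the same direction. As a set they showed no reversal of the salt effect, and both effects ran with dimmer arrays. Median scaling gave 3754 genes with 3569 higher, a fit of only the groups compared gave 95, array weights gave 597, genes detected on all arrays gave 174 higher and 84 lower, and the detected-probe covariate gave 188; the calls of Tgfb1, Spp1 and Ccn2 ended under at least 3 of these. On simulated data with each group's own spread, 38.8% to 41.9% of the calls in this comparison were false.

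On low salt, no ventricle gene was shown to change with the antibody. Tgfb1 (-0.10 ± 0.25), Nppa (0.23 ± 0.30), Spp1 (0.21 ± 0.39) and Col3a1 (-0.23 ± 0.24) did not pass. In limma 0 of 6517 genes passed and 56 had an unadjusted p under 0.05, and with array weights 8 passed. Chance alone gives such a p for a share of about 0.05 of the genes, and 56 is far fewer. The spread was pooled with high salt arrays, which correlated less within their groups (median r 0.936 and 0.953) than low salt arrays (0.988 and 0.983). This makes the test on low salt conservative, although a fit of only the groups compared did not change the count of genes passing. Ddit4 (0.64 ± 0.17), Limd1 (-0.52 ± 0.14), Tsc22d3 (0.52 ± 0.14), Pdk4 (1.11 ± 0.31) and Nfkbia (0.57 ± 0.18) had the smallest p-values and did not pass (adjusted p = 1). Of 15 macrophage genes 0 passed, also adjusted over the list alone, although the list mean of 0.18 had a camera adjusted p = 0.000301, with an adjusted p = 0.561 with an estimated correlation. Of 5 blood cell genes 0 passed, also adjusted over the list alone, with a mean of -0.22, a camera adjusted p = 0.0228 and an adjusted p = 0.561 with an estimated correlation. Both list calls were lost without the filter on detection.

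The antibody effect differed between diets in the ventricle for Fhl1 (-3.12 ± 0.60, adjusted p = 0.00597), Col8a1 (-2.74 ± 0.50, adjusted p = 0.00522) and Mrc1 (-2.49 ± 0.57, adjusted p = 0.0221), given as the effect on high salt minus that on low salt. As above, the high salt antibody arrays were mostly at background for Col8a1 and Mrc1. For Tgfb1 the difference of -0.79 ± 0.35 did not pass (adjusted p = 0.201). Of 15 macrophage genes 3 were lower and 0 higher (7 lower adjusted over the list alone), with a mean of -0.95, a camera adjusted p = 8.62e-05 and an adjusted p = 0.564 with an estimated correlation. Of 12 cardiac stress genes 2 were lower and 0 higher (3 lower adjusted over the list alone), with a mean of -0.77, a camera adjusted p = 0.0263 and an adjusted p = 0.630 with an estimated correlation. In all, 124 genes passed, 9 higher and 115 lower. With median scaling 1342 passed, of which 1303 were higher, array weights gave 452, no filter gave 54 and the detected-probe covariate gave 44. With this covariate the changes of the 124 genes had a median ratio of 0.881 to the unadjusted ones (quartiles 0.813 to 0.952), and 0.843 with only high salt arrays of overlapping brightness, with 0 genes reversed in either. Among genes detected on all arrays limma called 0, with 317 at an unadjusted p under 0.05.

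In the kidney, high salt raised genes of fibrosis and of tubular injury. Timp1, an inhibitor of matrix metalloproteinases (gene ID 116510; chromosome X, 3766509 to 3772578), rose by 2.02 ± 0.27 (adjusted p = 0.000426). Col3a1, the fibrillar collagen III (chromosome 9, 54866646 to 54902578), rose by 1.49 ± 0.22 (adjusted p = 0.000615) and Col1a1 by 1.31 ± 0.31 (adjusted p = 0.00678). Lcn2, a lipocalin released by injured tubules, rose by 1.81 ± 0.48, Serpina3n, an acute phase protease inhibitor, by 2.55 ± 0.51 and Fgb, fibrinogen beta, by 1.99 ± 0.38. Serpina3n was above background on 2 of 6 low salt and 6 of 6 high salt arrays, so the size of its change rests on values at background. For Timp1, Col3a1, Lcn2, Serpina3n and Fgb, each of the 6 high salt arrays lay above each of the 6 low salt arrays. Tgfb1 rose by 0.95 ± 0.27 (adjusted p = 0.0179), Fn1 by 1.15 ± 0.34 and Spp1 by 0.95 ± 0.24, while Ccn2 (0.05 ± 0.18) and Fli1 (-0.05 ± 0.14) did not pass. Cyp1a1, a xenobiotic-metabolizing cytochrome P450, fell by 2.10 ± 0.43, and Egf, a growth factor gene of the thick ascending limb, fell by 0.85 ± 0.19.

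**Figure D3:**
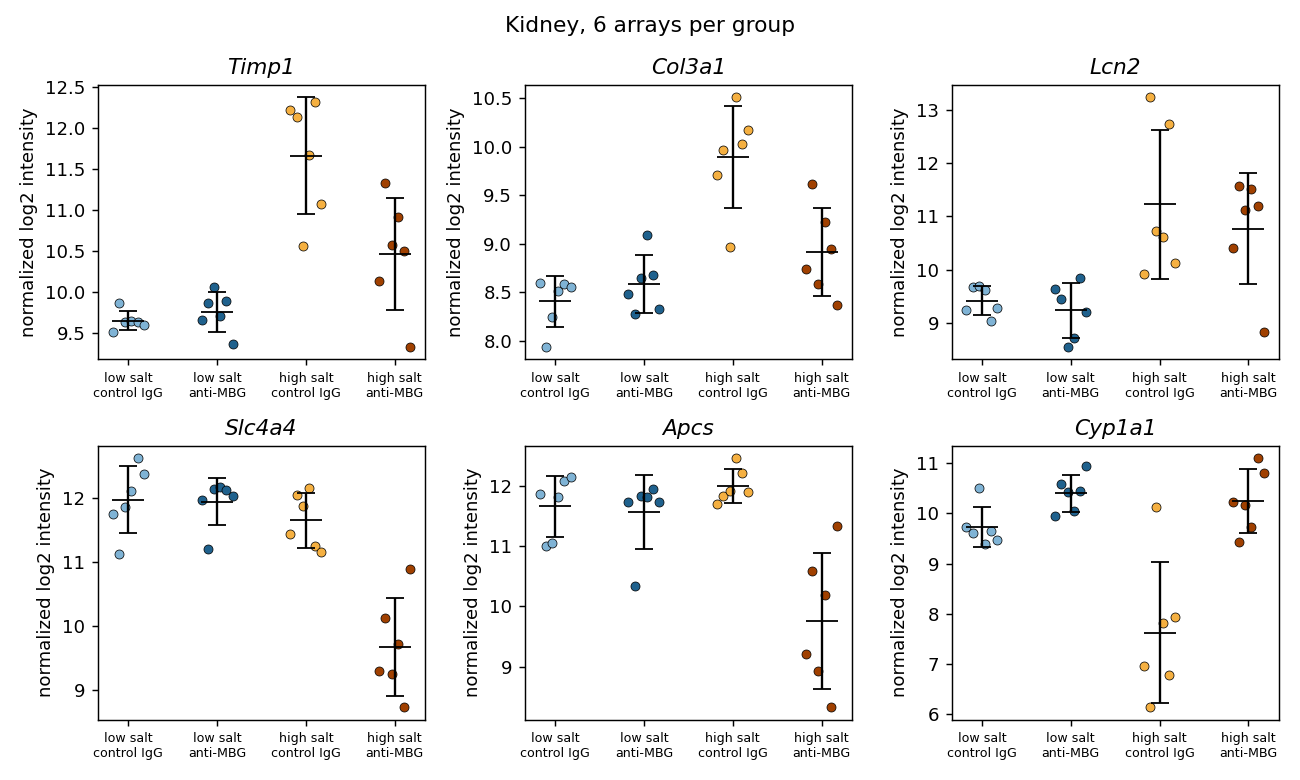
Normalized log2 intensity of 6 genes on each kidney array, by diet and antibody; points are arrays, horizontal lines are means and bars are SDs (n = 6). Timp1, Col3a1 and Lcn2 were higher on high salt under control IgG, Cyp1a1 was lower there, and Slc4a4 and Apcs were lower in each high salt antibody array than in each high salt control array.

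The tubular injury list had 15 of 23 measured members higher and 0 lower (18 higher adjusted over the list alone), with Tnfrsf12a, the TWEAK receptor, at 1.52 ± 0.24 and Vim at 0.71 ± 0.13. Its mean was 0.92, with a camera adjusted p = 3.89e-11 and an adjusted p = 0.154 with an estimated correlation. Complement and acute phase genes had 10 of 13 higher (11 adjusted over the list alone; mean 1.12, camera adjusted p = 2.90e-07), collagen genes 10 of 21 (13 adjusted over the list alone; mean 0.69, camera adjusted p = 1.32e-08) and matrix glycoproteins 10 of 18 (10 adjusted over the list alone; mean 0.68, camera adjusted p = 1.28e-05). Cell cycle genes had 11 of 16 higher (11 adjusted over the list alone; mean 0.73, camera adjusted p = 1.16e-08), with Ccnb2 at 1.17 ± 0.21, and fibroblast markers 6 of 12 (9 adjusted over the list alone; mean 0.79, camera adjusted p = 2.67e-05). None of these 5 lists had a lower member, and each had an adjusted p = 0.154 with an estimated correlation. Macrophage genes had 11 of 21 higher and 0 lower (14 higher adjusted over the list alone), with the galectin Lgals3 at 1.15 ± 0.25, a mean of 0.56, a camera adjusted p = 2.97e-07 and an adjusted p = 0.307 with an estimated correlation. TGF-beta induced genes had 6 of 18 higher and 1 lower (6 and 2 adjusted over the list alone), a mean of 0.37, a camera adjusted p = 0.0204 and an adjusted p = 0.446 with an estimated correlation. The lower member was Smad7, an inhibitor of TGF-beta signaling, which fell by 0.90 ± 0.18.

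Some nephron and respiratory genes were lower in the kidney on high salt. Of 8 thick ascending limb genes 4 fell and 0 rose (4 lower adjusted over the list alone), among them Umod, which fell by 0.38 ± 0.13 (mean -0.30, camera adjusted p = 0.0384, adjusted p = 0.410 with an estimated correlation). Of 23 proximal tubule genes 5 fell and 0 rose (5 lower adjusted over the list alone), among them the organic cation transporter Slc22a2, which fell by 0.83 ± 0.17 (mean -0.18, camera adjusted p = 0.0271, adjusted p = 0.524 with an estimated correlation). Of 26 oxidative phosphorylation genes 9 fell and 0 rose (13 lower adjusted over the list alone), among them Ndufv2, which fell by 0.33 ± 0.06 (mean -0.20, camera adjusted p = 6.58e-06, adjusted p = 0.326 with an estimated correlation). Adipocyte markers moved with the same groups: 3 of 8 were higher and 0 lower (4 higher adjusted over the list alone), with Cfd, adipsin, at 1.78 ± 0.51, a mean of 0.96, a camera adjusted p = 0.00665 and an adjusted p = 0.316 with an estimated correlation.

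In all, 1619 of 9800 kidney genes changed with high salt, 760 higher and 859 lower. A fit of only the groups compared gave 581, and with each group's own spread 21.8% to 24.9% of the calls on simulated data were false. The detected-probe covariate ended the calls of Tgfb1 (0.54), Lcn2 (1.503), Fn1 (1.15) and Spp1 (0.73), the adipocyte covariate ended those of Col1a1 (1.11) and Cfd (0.23), and Umod lost its call under 9 alternatives.

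With the antibody on high salt, some kidney collagens and matrix genes were lower and several tubule genes moved. Timp1 fell by 1.20 ± 0.27 (adjusted p = 0.0152), Col3a1 fell by 0.98 ± 0.22 (adjusted p = 0.0142) and Col1a1 fell by 1.12 ± 0.31 (adjusted p = 0.0410). Slc4a4, the basolateral sodium bicarbonate cotransporter (gene ID 84484; chromosome 14, 19125394 to 19577379), fell by 1.99 ± 0.29 (adjusted p = 0.00172), and Apcs, the pentraxin serum amyloid P, fell by 2.24 ± 0.37 (adjusted p = 0.00401). Cyp1a1 rose by 2.62 ± 0.43 (adjusted p = 0.00401) and Slc22a13, an organic anion transporter, rose by 1.76 ± 0.31 in the fit, with 6 of 6 antibody arrays and 1 of 6 control arrays above background. For Slc4a4, Apcs and Slc22a13 the 6 antibody and 6 control arrays did not overlap. Tgfb1 (-0.84 ± 0.27, adjusted p = 0.0758), Lcn2 (-0.46 ± 0.48), Fn1 (-0.62 ± 0.34), Spp1 (-0.07 ± 0.24), Ccn2 (0.22 ± 0.18) and Fli1 (-0.39 ± 0.14) did not pass.

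Collagen genes had 7 of 21 members lower and 0 higher (13 lower adjusted over the list alone), with Col14a1 at -1.78 ± 0.38, a mean of -0.60, a camera adjusted p = 6.13e-11 and an adjusted p = 0.0882 with an estimated correlation. Fibroblast markers had 6 of 12 lower (7 adjusted over the list alone; mean -0.77, camera adjusted p = 3.13e-08, adjusted p = 0.0813 with an estimated correlation) and matrix glycoproteins 6 of 18 lower (9 adjusted over the list alone; mean -0.61, camera adjusted p = 5.59e-07, adjusted p = 0.0882 with an estimated correlation), with 0 higher in either. TGF-beta induced genes had 6 of 18 lower and 1 higher (6 and 1 adjusted over the list alone), with a mean of -0.39, a camera adjusted p = 2.25e-05 and an adjusted p = 0.155 with an estimated correlation. Their higher member was Tgfbi, a secreted matrix protein, which rose by 0.93 ± 0.20, and Tagln, a smooth muscle actin-binding protein, fell by 1.03 ± 0.21. Tubular injury genes had 3 of 23 lower and 0 higher (5 lower adjusted over the list alone; mean -0.51, camera adjusted p = 4.31e-08, adjusted p = 0.155 with an estimated correlation). Adipocyte markers again moved with the group, with 3 of 8 lower and 0 higher (5 lower and 1 higher adjusted over the list alone; mean -1.004, camera adjusted p = 0.00357, adjusted p = 0.275 with an estimated correlation). Ucp1, the brown fat uncoupling protein, was above background on 4 of 6 control and 0 of 6 antibody arrays, and its mean was at least 5.34-fold lower (adjusted p = 0.0477). The control arrays spread widely (8.79 ± 2.98, SD), so this bound holds for the mean and not for each array. On low salt Ucp1 was above background on 2 of 6 arrays of each group.

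Some distal nephron genes were higher with the antibody on high salt. The thick ascending limb list had 4 of 8 members higher and 0 lower (5 higher adjusted over the list alone), with Egf at 0.95 ± 0.19 and Umod, uromodulin, at 0.52 ± 0.13 (mean 0.59, camera adjusted p = 1.12e-05, adjusted p = 0.0882 with an estimated correlation). The distal tubule and collecting duct list had 5 of 18 higher and 0 lower (7 higher adjusted over the list alone), with Scnn1a, a subunit of the epithelial sodium channel, at 0.73 ± 0.16 (mean 0.43, camera adjusted p = 4.24e-06, adjusted p = 0.0882 with an estimated correlation). Proximal tubule genes went both ways, 3 higher and 5 lower of 23 (4 and 8 adjusted over the list alone; mean -0.35, camera adjusted p = 0.0266, adjusted p = 0.527 with an estimated correlation). Besides Slc4a4, the glucose transporter Slc5a2 fell by 1.33 ± 0.32 and the glucose 6-phosphatase gene G6pc1 fell by 1.06 ± 0.27, while the amino acid transporter subunit Slc3a1 rose by 0.32 ± 0.08.

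**Figure D4:**
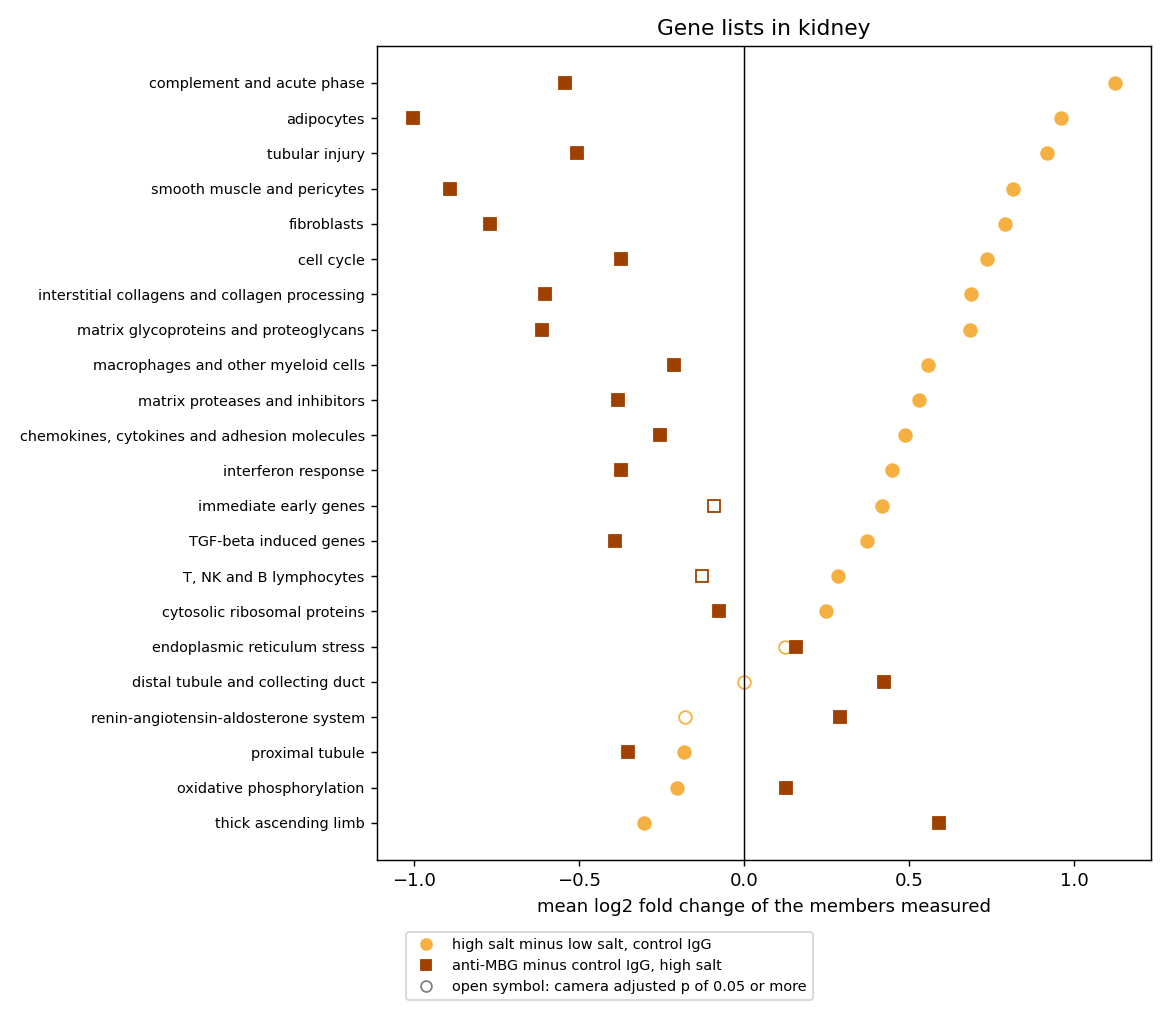
Mean log2 fold change of the measured members of each gene list in kidney, for high salt (circles) and for the antibody on high salt (squares); filled symbols passed the camera test at its preset correlation, and no list passed with an estimated correlation. The mean of the collagen list was 0.69 with high salt and -0.60 with the antibody, and that of the thick ascending limb list was -0.30 and 0.59.

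In all, 371 of 9800 kidney genes changed with the antibody on high salt, 226 higher and 145 lower. Array weights gave 1199 genes, a fit of only the groups compared gave 52 and ended the calls of Timp1, Col3a1 and Col1a1, the detected-probe covariate gave 230, and the adipocyte covariate gave 117 and ended the calls of Col3a1 (-0.98) and Col1a1 (-0.91). Without replicate 2 of the low salt control group 741 genes passed, and without it and replicate 1 of the high salt control group 703 passed. Replicate 2 of the low salt control group is in neither group of this comparison. Leaving it out changed only the pooled spread and not the fold changes.

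On low salt, no kidney gene was shown to change with the antibody. Timp1 (0.11 ± 0.27), Col3a1 (0.18 ± 0.22), Tgfb1 (0.24 ± 0.27) and Lcn2 (-0.18 ± 0.48) did not pass. In limma 0 of 9800 genes passed and 1642 had an unadjusted p under 0.05, with array weights 1343 passed and with median scaling 1. The 1642 genes are more than the share of about 0.05 that chance alone gives, so changes too small to pass are not excluded. The cause of this excess was not tested. The smallest p-values were those of Tspan4 (1.01 ± 0.20), Tas2r7l (0.51 ± 0.10), Rnf138 (-1.11 ± 0.22), Gatd1 (0.67 ± 0.13) and Spetex2b (-1.16 ± 0.23), each with an adjusted p = 0.0668; Rnf138 and Spetex2b were above background on 1 of 6 antibody and 6 of 6 control arrays.

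The antibody effect differed between diets in the kidney for Slc4a4 (-1.96 ± 0.41, adjusted p = 0.0254), Apcs (-2.14 ± 0.52, adjusted p = 0.0408), Slc22a13 (2.15 ± 0.43, adjusted p = 0.0177) and the glutathione transferase Gstm1 (-1.65 ± 0.29, adjusted p = 0.0144), given as the effect on high salt minus that on low salt. The size for Slc22a13 again rests on control arrays at background. The differences of Timp1 (-1.31 ± 0.38, adjusted p = 0.0625), Col3a1 (-1.16 ± 0.31, adjusted p = 0.0510), Tgfb1 (-1.08 ± 0.38, adjusted p = 0.103) and Col1a1 (-0.63 ± 0.43, adjusted p = 0.413) did not pass. Of the 8 thick ascending limb genes 1, Egf, was higher (1.22 ± 0.27; 5 higher adjusted over the list alone), with a mean of 0.63, a camera adjusted p = 0.00132 and an adjusted p = 0.487 with an estimated correlation. Of 12 fibroblast markers 0 passed (4 lower adjusted over the list alone; mean -0.82, camera adjusted p = 0.00102, adjusted p = 0.487 with an estimated correlation). Of 21 collagen genes 0 passed (3 lower adjusted over the list alone; mean -0.44, camera adjusted p = 0.00124, adjusted p = 0.607 with an estimated correlation). Markers of other cell types moved the same way, with 0 of 5 blood cell genes passing (0 adjusted over the list alone; mean -1.14, camera adjusted p = 0.0437, adjusted p = 0.607 with an estimated correlation) and 0 of 8 adipocyte markers (4 lower adjusted over the list alone; mean -1.10, camera adjusted p = 0.0197, adjusted p = 0.607 with an estimated correlation). In all, 158 genes passed, 104 higher and 54 lower. Array weights gave 1439 genes, median scaling 353, the detected-probe covariate 363, the authors' values 68 and no filter 49; without replicate 2 of the low salt control group 337 passed, and without it and replicate 1 of the high salt control group 356.

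Kidney genes that changed with salt and with the antibody on high salt went in opposite directions. Of the genes raised by salt, Timp1 and Col3a1 among them, 71 were lowered by the antibody. Of the genes lowered by salt, Cyp1a1 and Slc22a13 among them, 144 were raised by the antibody, and 0 genes moved the same way. Both effects use the high salt control arrays with opposite sign, which by itself favors opposite directions. Across 9800 genes, which are not independent replicates, the effects had r = -0.66. The shared arrays alone gave a mean r of -0.49 in 100 simulations without effects, from -0.89 to 0.09. With these arrays split between the effects the median r was -0.42. In the ventricle r was 0.26 across 6517 genes, against a mean of -0.48 in simulations, and both effects ran with dimmer arrays.

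**Figure D5:**
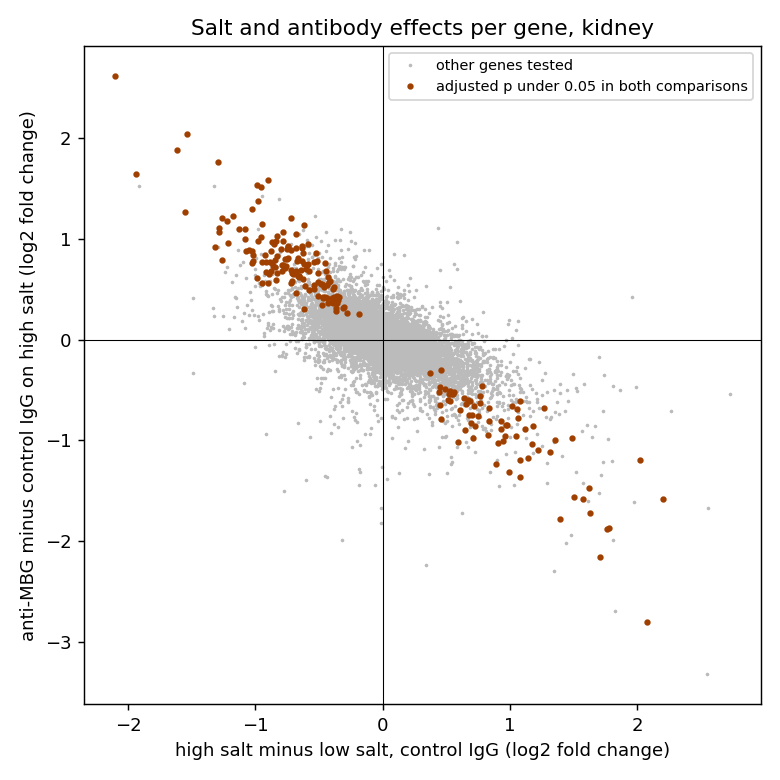
Log2 fold change of each kidney gene with the antibody on high salt (vertical axis) against that with high salt under control IgG (horizontal axis); colored points passed in both comparisons. The 71 genes raised by salt and lowered by the antibody and the 144 genes lowered by salt and raised by the antibody lie in opposite quadrants; both axes share the high salt control arrays.

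The salt effect differed between the tissues of the same animals for 4 of 8 genes fixed for naming. Timp1 had a salt effect of 2.06 in kidney and 0.53 in ventricle when both tissues were normalized together, a difference of 1.52 ± 0.49 (adjusted p = 0.00746). Col3a1 had effects of 1.47 and 0.23, a difference of 1.23 ± 0.32 (adjusted p = 0.00134). Tgfb1 had effects of 0.86 and 1.94, a difference of -1.08 ± 0.38 (adjusted p = 0.0144), and Fli1 effects of -0.05 and 1.10, a difference of -1.15 ± 0.25 (adjusted p = 0.000114). The differences of Ccn2 (-0.33 ± 0.30), Fn1 (1.02 ± 0.66), Spp1 (-0.52 ± 0.51) and Lcn2 (1.03 ± 0.63) did not pass. In all, 3405 of 6200 genes tested in both tissues differed, 2176 with a higher effect in kidney and 1229 with a lower effect, and 3340 with the animal as a block. With each group's own spread, 13.6% to 19.2% of the calls in this comparison on simulated data were false. The median difference over all genes was 0.33, and the ventricle arrays differed in brightness by diet. Without a filter 5133 genes passed, and among genes detected on all arrays 1106 (417 higher and 689 lower). Median scaling gave 1354 higher and 1915 lower with a median difference of -0.16. The balance turned with detection on all arrays and with median scaling. With the authors' values Tgfb1 no longer passed, at a difference of -0.21 in z scores.

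The antibody effect on high salt differed between tissues for Slc4a4, at -2.03 in kidney and 0.08 in ventricle (difference -2.11 ± 0.41, adjusted p = 0.000526), and for Fhl1, at -0.12 and -3.10 (difference 2.99 ± 0.66, adjusted p = 0.00170; above background on 3 of 6 ventricle antibody arrays). Tgfb1 had effects of -0.77 and -0.87, and the difference of 0.10 ± 0.38 did not pass. Col3a1 (difference -0.75 ± 0.32, adjusted p = 0.0998) and Spp1 (1.27 ± 0.51, adjusted p = 0.0749) did not pass either. In all, 1056 of 6200 genes differed, 847 higher and 209 lower in kidney, and 978 with the animal as a block. Median scaling gave 2916 genes with 115 higher, array weights 594 (without Slc4a4), only the groups compared 143 (without Fhl1) and genes detected on all arrays 112 (38 higher and 74 lower). On simulated data with each group's own spread, 40.3% to 49.7% of the calls in this comparison were false.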

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

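Some tests were chosen only after the data or a result had been seen. They were those of the detected-probe covariate, the ventricle arrays of overlapping brightness, the simulated shared control arrays in kidney and the kidney control arrays left out. The others were those of the adipocyte covariate and the lists without an array that stood apart, and the glucocorticoid test among the other observations. Arrays were looked at for values far from the other 5 of their group, judged by the gap to the nearest array relative to the range of the group. In 14 of 216 groups an array stood apart, and chance alone does so in about 1 in 20 groups. In the ventricle these were Nppb at 11.94 in low salt antibody replicate 3 (others 12.50 to 12.81), Fli1 at 6.57 in low salt control replicate 1 (others 7.46 to 7.84), Spp1 at 5.44 in high salt antibody replicate 3 (others 7.08 to 7.94), Timp1 at 5.50 in high salt antibody replicate 4 (others 7.57 to 8.26) and Fn1 at 6.30 in high salt antibody replicate 1 (others 5.001 to 5.289). List scores stood apart there for adult cardiomyocyte genes at 11.63 in low salt control replicate 1 (others 11.44 to 11.50) and for oxidative phosphorylation at 12.38 in high salt control replicate 1 (others 11.75 to 11.98). In the kidney these were Fli1 at 8.57 in high salt control replicate 3 (others 8.93 to 9.12), Fn1 at 9.73 in high salt antibody replicate 6 (others 11.10 to 11.51) and the number of detected probes at 9672 in low salt antibody replicate 1 (others 8389 to 8801). Kidney list scores stood apart for TGF-beta induced genes at 9.55 in high salt control replicate 3 (others 9.90 to 10.05), blood cell genes at 12.49 in low salt control replicate 1 (others 9.55 to 10.60), and ribosomal proteins at 12.92 (others 13.41 to 13.46) and oxidative phosphorylation at 13.18 (others 13.39 to 13.50), both in low salt control replicate 2. Without the array that stood apart, all camera calls of these lists at the preset correlation remained, and in kidney blood cell genes (high salt 1.25, antibody on low salt 0.89) and TGF-beta induced genes (difference between diets -0.30) passed camera in addition, at adjusted p = 0.236, 0.954 and 0.564 with an estimated correlation.

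Effects that differed between groups by a test of the difference itself were those of the antibody between diets, with 124 genes in ventricle and 158 in kidney, and those between tissues, with 3405 genes for high salt and 1056 for the antibody on high salt. Among the genes fixed for naming, the salt effect differed between tissues for Timp1 (1.52), Col3a1 (1.23), Tgfb1 (-1.08) and Fli1 (-1.15). In 100 splits of the arrays, the real split included, as many genes were called in 1 split for high salt in ventricle (highest other 3640 against 4156), 2 for the antibody on high salt in ventricle (1536 against 1376), 2 for its difference between diets (747 against 124), 1 for high salt in kidney (266 against 1619), 1 for the antibody on high salt in kidney (263 against 371) and 4 for its difference between diets (484 against 158). Between tissues it was 1 split for high salt (2594 against 3405) and 2 for the antibody (1118 against 1056). On low salt the real count was 0, which every split reaches by definition, so the splits decide nothing there. The highest other counts were 1 gene in ventricle and 383 in kidney. Splits with several times the real count, as for both differences between diets, point to structure among the arrays, whose cause was not tested. With labels exchanged only within each diet it is not the diet effect itself.

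The ventricle changes with the antibody on high salt, Fhl1 and Col8a1 among them, went with fewer detected probes in the antibody group, 3010 against 4026 of the control group. With the number of detected probes as a covariate the median ratio of adjusted to unadjusted change over the 1376 genes was 0.612, and with only 3 antibody and 4 control arrays of overlapping brightness it was 0.643. These values leave brightness possible as a part of the effect, and an antibody effect on the tissue remains possible as well. Fhl1 and Col8a1 kept their calls with the covariate.

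The ventricle changes with high salt, Nppa and Tgfb1 among them, went with arrays that were dimmer without overlap. With the covariate the median ratio over the 4156 genes was 0.290, and without overlap this value decides nothing between brightness and diet. The natriuretic peptides could reflect the load of the heart on high salt, and the arrays give no means of testing this apart from brightness.

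In the kidney the opposite effects of salt and antibody, Timp1 and Slc22a13 among the genes, may reflect a reversal of salt-induced injury by the antibody or the high salt control arrays that both effects share. The covariance of the effects was -0.0755, just below the lowest of -0.0745 in 100 simulations in which arrays drawn from all groups stood for the shared ones. With the high salt control arrays split, the median covariance was -0.0540, within the simulated range of -0.0596 to 0.0213. The high salt control arrays correlated less with each other than those of the other groups, so both ranges may be too narrow, and shared arrays remain possible. High salt control replicate 1 and low salt control replicate 2, which correlated least with their groups (median r 0.947 and 0.931), were not the whole cause, since 0.848 of the covariance difference remained without them, and 0.887 to 1.43 with each high salt control array left out in turn. Fat in the high salt control kidneys, a possible source of their higher adipocyte markers (mean 0.96), was not the whole cause either, since the median ratio over 215 genes with the adipocyte score as a covariate was 1.02 (quartiles 0.916 to 1.15). The high salt control group also detected the most probes of the kidney groups. With the detected-probe covariate the median ratio was 0.936 over the 1619 genes of high salt and 0.957 over the 371 of the antibody on high salt. Most of each change thus remained, and the opposite directions themselves were not tested with this covariate.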

How the results depend on the processing

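Counts stayed within 1.5 times, and correlations within the SD of simulations, in 35 of 51 values in ventricle, 46 of 64 in kidney and 14 of 20 between tissues. List results stayed the same in 584 of 668 values in ventricle (25 weaker, 56 stronger, 3 reversed) and 789 of 888 in kidney (74 weaker, 23 stronger, 2 reversed). Results of named genes stayed the same in 1320 of 1526 values in ventricle (175 weaker, 25 stronger, 6 reversed), 3656 of 4089 in kidney (260 weaker, 173 stronger, 0 reversed) and 467 of 508 between tissues (29 weaker, 9 stronger, 3 reversed). A list or gene that passed in neither fit also counted as the same, so these shares do not measure how often a call held. With an estimated correlation all list calls were lost, 11 in ventricle and 56 in kidney. Signal over background limits the ventricle most, where 1843 genes were detected on all arrays against 7116 in kidney. The authors' values in the series matrix were identical and not run again, the files name no chip to use as a block, and a fit of only the groups compared does not apply to differences between diets, which use all 4 groups. Replicate numbers within a tissue were treated as names only. Arrays correlated best with their own number in 2 of 24 cases in ventricle and 6 of 24 in kidney, and the number for unrelated names was not computed. Pairs with the same number had a median r of -0.0171 in ventricle and -0.0187 in kidney. An r over 0.1 was found in 11.1% of these pairs in ventricle and 36.1% in kidney, so a link by number is not excluded. Unless stated, the cause of a move was not tested.

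For the antibody on high salt in ventricle (1376 genes) median scaling gave 3754, detection on all arrays 174 higher and 84 lower, about 2.6e+02 in all (fewer genes tested), array weights 597, only the groups compared 95, the detected-probe covariate 188 and arrays of overlapping brightness 438 (fewer arrays). The share of higher genes was 28.4%, and 95.1% with median scaling. For high salt in ventricle (4156) detection on all arrays gave 1373 (fewer genes tested) and the covariate 97; the share of higher genes was 38.4%, 64.2% with detection on all arrays, 64.7% with median scaling and 26.1% with the authors' values. For the antibody on low salt in ventricle (0) array weights gave 8. For its difference between diets in ventricle (124) median scaling gave 1342, the authors' values 223, no filter 54 (more genes tested), detection on all arrays 0, with limma calling 317 at an unadjusted p under 0.05, array weights 452, replicate numbers as a block 70 and the covariate 44.

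For high salt in kidney (1619) only the groups compared gave 581; the share of higher genes was 46.9%, and 63.7% with the authors' values. For the antibody on high salt in kidney (371) array weights gave 1199, only the groups compared 52, the detected-probe covariate 230, the adipocyte covariate 117 and leaving out both control arrays of low correlation with their groups 703; leaving out 1 of them gave 273 (high salt control replicate 1) or 741 (low salt control replicate 2). The rise to 741 came from the pooled spread alone, since that array is in neither group compared. The share of higher genes for the antibody on high salt was 60.9%, and 46.1% with the authors' values. For the antibody on low salt in kidney (0) median scaling gave 1 and array weights 1343. For its difference between diets in kidney (158) median scaling gave 353 (43.3% higher against 65.8%), the authors' values 68, no filter 49 (more genes tested), array weights 1439, replicate numbers as a block 42, the detected-probe covariate 363, both arrays left out 356, and 1 of them left out 176 (high salt control replicate 1) or 337 (low salt control replicate 2). The correlation of salt and antibody effects in kidney (-0.66) was -0.42 with the high salt controls split, which then no longer share arrays.

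Between tissues, high salt (3405, 63.9% higher) gave 5133 without a filter (more genes tested) and 1106 with detection on all arrays (37.7% higher; fewer genes tested), and 41.4% were higher with median scaling. The antibody on high salt (1056) gave 2916 with median scaling (3.94% higher), 112 with detection on all arrays (fewer genes tested), 594 with array weights and 143 with only the groups compared.

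Some results turned direction. In ventricle, median scaling called 7.96% of the 4156 genes of high salt and 17.9% of the 1376 of the antibody on high salt the other way, and the authors' values 0.698% of the 4156. Among named genes and lists, with median scaling, for the antibody on high salt in ventricle, these were oxidative phosphorylation (0.12), Loxl2 (0.49), Fn1 (0.23), Tpm3 (0.31) and Cd14 (0.61), for its difference between diets Cd14 (0.22), and between tissues Clec4a3 (-0.17) and Adnp (-0.0911). With the authors' values, in z scores, these were adult cardiomyocyte genes (-0.25) and oxidative phosphorylation (0.16) for high salt in ventricle, the directions being relative to all genes. In kidney it was oxidative phosphorylation for the antibody on low salt (0.13) and for its difference between diets (-0.00837). Between tissues it was Lum for the antibody (0.00158). With the covariate 1180 of the 4156 genes changed sign for high salt in ventricle, among them Ola1 (0.0300), the only called gene among those named. Median scaling also raised the median of all ventricle genes for the antibody on high salt, so the sign changes of single genes there go with a shift of all genes. Loxl2 and Cd14 had no array above background in either high salt group, and Fn1 none with the antibody. Their values are therefore differences at background.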

Other observations

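In the kidney, some inflammatory genes were higher on high salt. The chemokines Ccl21 and Ccl20 rose by 1.62 ± 0.29 and 1.58 ± 0.31 (n = 6), with Ccl20 above background on 2 of 6 low salt and 6 of 6 high salt arrays, and 5 of 22 chemokine, cytokine and adhesion genes rose and 0 fell (6 higher adjusted over the list alone; mean 0.49, camera adjusted p = 0.000330, adjusted p = 0.259 with an estimated correlation). Interferon response genes had 7 of 19 higher and 0 lower (12 higher adjusted over the list alone; mean 0.45, camera adjusted p = 7.00e-06, adjusted p = 0.316 with an estimated correlation), with the antiviral membrane protein Ifitm1 at 0.90 ± 0.19. The T cell receptor subunit Cd3e rose by 0.60 ± 0.16, and lymphocyte genes had 2 of 13 higher and 0 lower (2 higher adjusted over the list alone; mean 0.29, camera adjusted p = 0.0204, adjusted p = 0.316 with an estimated correlation). Ribosomal protein genes had 6 of 23 higher and 0 lower (9 higher adjusted over the list alone; mean 0.25, camera adjusted p = 2.41e-06, adjusted p = 0.259 with an estimated correlation), with Rps3 at 0.59 ± 0.13. Low salt control replicate 2 stood apart on this list, and without it the mean was 0.16, with 5 higher and a camera adjusted p = 1.43e-05.

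With the antibody on high salt, the kidney had more Agt, the angiotensinogen gene (0.89 ± 0.21), more Mme, the peptidase neprilysin (0.95 ± 0.20), and more Nr3c2, the mineralocorticoid receptor (0.42 ± 0.12). The renin-angiotensin-aldosterone list had 3 of 9 members higher and 0 lower (3 higher adjusted over the list alone; mean 0.29, camera adjusted p = 0.00357, adjusted p = 0.0882 with an estimated correlation). Smooth muscle genes had 2 of 8 lower and 0 higher (5 lower adjusted over the list alone; mean -0.89, camera adjusted p = 1.05e-05, adjusted p = 0.0882 with an estimated correlation), with the myosin light chain Myl9 at -0.96 ± 0.27. Ccl21 fell by 1.47 ± 0.29. Interferon response genes had 0 of 19 passing in limma (5 lower adjusted over the list alone; mean -0.37, camera adjusted p = 4.24e-06, adjusted p = 0.287 with an estimated correlation).

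The test of a glucocorticoid signal was chosen only after the result was seen. Ddit4 (0.64), Tsc22d3 (0.52), Pdk4 (1.11) and Nfkbia (0.57), which glucocorticoids induce, had small p-values with the antibody on low salt in ventricle and did not pass. If glucocorticoids were higher in these animals, other induced genes might be higher in both tissues. A list was written from general knowledge, and the 6 genes already seen were left out; the last of these, Cebpb, was removed after a first result, because it turned out to have been seen. In ventricle 8 of 9 measured genes had a positive change (mean 0.12), with a camera p of 0.0195 (0.0247 with an estimated correlation), and in kidney 7 of 13 (mean 0.07), with a camera p of 0.516 in kidney. Of single genes in kidney, Ddit4 (0.58) and Fkbp5 (0.59), both left out of the list, and Sgk1 (0.61) were higher and did not pass (adjusted p = 0.119, 0.127 and 0.160). With the antibody on high salt the kidney list was lower, with 4 of 13 positive, a mean of -0.25 and a camera p of 0.0105 (0.0424 with an estimated correlation). A p of 0.05 or more in kidney had been written as evidence against the explanation, but a test that misses its threshold excludes nothing. The verdict was therefore changed to open after the result was seen, and a glucocorticoid signal remains possible and unshown.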
